A study of Homo sapiens with 36 samples.

How the data were processed

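Total RNA of TC32 cells was extracted, labelled as cRNA and hybridized to Illumina HT-12 bead arrays, 36 in all, 48 h after transfection. Per the labels, all arrays had a dose of 20 nM, Untreated ones included, and the groups were 3 Untreated arrays (taken as untransfected from the treatment text), 6 siNeg arrays and 3 arrays for each of 9 siRNAs, 3 siRNAs per targeted gene. The first deposited file held the average bead signal intensity of 47323 probes per array, neither background-subtracted nor normalized. It also held a deposited detection p-value for each intensity, in steps of 1/770. A second table held log2 values that the authors had normalized with R 3.0.2 and lumi, by a method the labels do not state. It had 47231 probes. In it 24 arrays shared one distribution (median 6.533) and 12 another (median 6.44): siNeg replicates 1 to 3 (set 1), Untreated, siSUPT6H and siSF3B1 in run 1, siNeg replicates 4 to 6 (set 2) and siHNRNPH1 in run 2. In the first file the Untreated columns were the only names left once all others had been matched to the labels. That the columns of both tables named the same arrays was checked by rank correlation: for 36 of 36 arrays the best match was its own column, with a coefficient of at least 0.9997.

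The deposited intensities were background-corrected and quantile-normalized together with neqc of limma 3.58.1 in R 4.3.3, which fits the background from the detection p-values. A probe was kept where its detection p was below 0.01 on at least 3 of 36 arrays (19738 probes). Gene symbols came from the platform's annotation, brought up to date by Entrez number. Of all probes 30113 had 1 symbol, 8 had several and 17202 had none, and the latter 2 kinds were left out of gene results. For 3008 genes with more than 1 kept probe the probe with the highest mean over all arrays stood for the gene, which left 11437 genes from 15211 probes.

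One limma model with 11 groups was fitted to all 36 arrays (25 residual degrees of freedom), with eBayes and an intensity trend. For each target the mean of its 3 siRNA groups was compared with the 6 siNeg arrays, and each siRNA singly. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and called with all 3 siRNAs where each was called with the same sign. Differences between targets, between siNeg and Untreated, and moderated F tests among the 3 siRNAs of a target came from the same fit. All limma tests were two-sided. The comparison of siNeg set 2 with set 1 came from the same data with the sets as separate groups. Own-run values compared siSUPT6H, siSF3B1 and Untreated with set 1 and siHNRNPH1 with set 2. They were added after the data had been seen, since the 2 runs were not known before.

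Gene lists were written before the data were examined and tested with camera of limma (inter-gene correlation 0.01), adjusted over 96 tests, and again with the correlation estimated and with fry. The 25 lists were EWS-FLI1 activated targets, EWS-FLI1 repressed targets, transcription elongation factors, U2 snRNP and SF3B components, other core spliceosome components, hnRNP genes, SR proteins and SR kinases, histone genes, p53 target genes, DNA replication and G1/S genes, G2/M and mitosis genes, BCL2 family genes, interferon response genes, integrated stress and unfolded protein response genes, heat shock genes, immediate early genes, intronless genes, ribosomal protein genes, cholesterol synthesis genes, nonsense-mediated decay factors, neuronal differentiation genes, extracellular matrix and mesenchymal genes, epithelial markers, blood cell markers and skeletal muscle markers. The last had 0 of 15 genes measured and was not tested. Tests of list differences between targets formed their own family of 72.

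The samples' groups, the main design, the rule for named genes and most alternatives were also fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls among genes called with all 3 siRNAs of a target, 10 each way between siNeg and Untreated, 8 each way for all 9 siRNAs, 4 each way between targets and between siNeg sets, the 6 smallest p of each F test, and the 4 members of a list with the largest changes. SUPT6H, SF3B1, HNRNPH1, EWSR1, FLI1, HNRNPH2, HNRNPF and SUPT5H were named whatever their result, and genes with only a placeholder name were passed over. Small RNA classes and their genes were chosen after the values had been seen. A gene undetected on every array of a group is given as a lower bound of its fold change.

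Between 13106 and 16788 probes were detected per array (14426 to 15901 in run 2), and arrays of a group correlated at 0.967 to 0.995. Simulated data of the same size, with the spread of arrays within a group, were used for a test of power. They held no shift between siNeg sets, no differences among the siRNAs of a target in the comparisons with siNeg and no correlation between genes. The recovered shares are therefore best cases. With siSUPT6H 89.6% of changes of 0.5, and 100% of changes of 1 or more, were recovered by the mean of 3 siRNAs, and 49.3 and 97% by all 3 siRNAs. Between siNeg and Untreated 65.7% were recovered at 0.5. Of the lists shifted by 0.5, 20 of 20 were called. The 3 arrays per siRNA limit precision, and the labels do not say whether replicates were separate cultures.

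Alternatives were quantile normalization of log2 (signal + 16) without background correction, the authors' values within a run, no detection filter or one by group, every kept probe, no intensity trend, array weights (statmod 1.5.0), the replicate number as a block, other control arrays, only the arrays of a comparison, siRNA means as replicates, siRNA as a random block, a minimum change of 1.5-fold, each array or siRNA left out, and separate control arrays for each target. Probe sequences, splice isoforms and probes without a gene symbol were left out of gene results, because the arrays mostly hold few probes per gene and those probes have no gene name in the annotation used.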

Results

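Genome-wide mRNA levels of TC32 Ewing sarcoma cells were measured on 36 Illumina bead arrays, 48 h after transfection with siRNA at 20 nM. SUPT6H, SF3B1 and HNRNPH1 were each silenced with 3 siRNAs on 3 arrays apiece (siSUPT6H_A1, A3 and Q3, siSF3B1_A2, A3 and Q3, siHNRNPH1_A2, A3 and Q3). The controls were 6 arrays of a negative control siRNA (siNeg) and 3 of cells labelled Untreated. The Untreated labels carry the same 20 nM dose as all others. They were taken as untransfected from the group name and the treatment text. Between 13106 and 16788 of 47323 probes were detected per array, the median raw signal was 83.8 to 96, and 11437 genes were measured. The siNeg arrays came as 2 sets of 3: set 1 belonged with the Untreated, siSUPT6H and siSF3B1 arrays, and set 2 with the siHNRNPH1 arrays (run 1 and run 2, as the authors normalized them). The main comparisons used all 6 siNeg arrays. Own-run values, from the siNeg set of the same run, are given beside them where they change a call or a size by much. All changes are log2 fold changes, and every adjusted p is from a two-sided limma test.

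The first question was whether each siRNA lowered its own mRNA. SUPT6H, which encodes a histone chaperone of elongating RNA polymerase II, averaged 5.08 (SD 0.51, n = 9 arrays) with siSUPT6H and 6.83 (SD 0.18, n = 6) with siNeg, a change of -1.75 (SE 0.09, adjusted p = 5.32e-19) that left 29.7% of the control level (95% interval 26.2 to 33.8). SF3B1, a U2 snRNP protein that helps to recognize the branch point of introns, fell by 1.48 with siSF3B1 (SE 0.08, adjusted p = 5.15e-18), to 35.8% of control (31.8 to 40.4). HNRNPH1, which encodes a splicing regulator that binds G-rich RNA, fell by 1.21 with siHNRNPH1 (SE 0.09, adjusted p = 6.79e-15), to 43.3% (38.3 to 48.8). In own-run values the 3 changes were -1.77, -1.29 and -1.35. Against all 6 siNeg arrays the other kept probe of HNRNPH1 gave -1.84 with siHNRNPH1, and that of SF3B1 -1.71 with siSF3B1. Each array of the targeted group lay below the lowest siNeg array: at most 5.81 against 6.53 for SUPT6H, 8.18 against 9.10 for SF3B1 and 9.04 against 9.67 for HNRNPH1. The siSUPT6H siRNAs were unequal, with at most 26.1% of SUPT6H mRNA left by A1 (detected on 0 of 3 arrays), 25.6% by A3 (2 of 3) and 46.7% by Q3 (3 of 3). The 95% intervals above rest on the spread of arrays within a group and leave out this spread among siRNAs. The same holds, here and below, for the SE and adjusted p of every mean of 3 siRNAs and of every difference between targets. The siSF3B1 siRNAs left 37.3, 34.7 and 35.5% of SF3B1, and the siHNRNPH1 siRNAs 43.4, 45.2 and 41.3% of HNRNPH1. SUPT6H was above background on 5 of its 9 siSUPT6H arrays, and the 4 others read at background level. The size of its fall depended on how the background was handled: -0.72 without background correction and -0.87 in the authors' values.

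The targeted mRNAs also changed with siRNAs against the other targets. SUPT6H mRNA fell by 1.12 with siSF3B1 (46.2% of control, adjusted p = 1.07e-13) and dropped by 0.80 with siHNRNPH1 (57.5%, adjusted p = 1.52e-09), with own-run values of -1.14 and -0.78. HNRNPH1 fell by 0.73 with siSUPT6H (adjusted p = 3.56e-09; own-run -0.59), although its other probe gave -0.14. SF3B1 changed by -0.33 with siSUPT6H (adjusted p = 0.00099), which own-run values did not call (-0.14, adjusted p = 0.191). HNRNPH1 changed by -0.20 with siSF3B1 (adjusted p = 0.0386), not called in own-run values either (-0.06, adjusted p = 0.609) and opposite on its other probe (0.39). SF3B1 was not called with siHNRNPH1 (0.10, adjusted p = 0.303), its other probe giving -0.32. It was called against siNeg set 1 (0.29, adjusted p = 0.00394) and against Untreated (0.21, adjusted p = 0.0398).

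**Figure D1:**
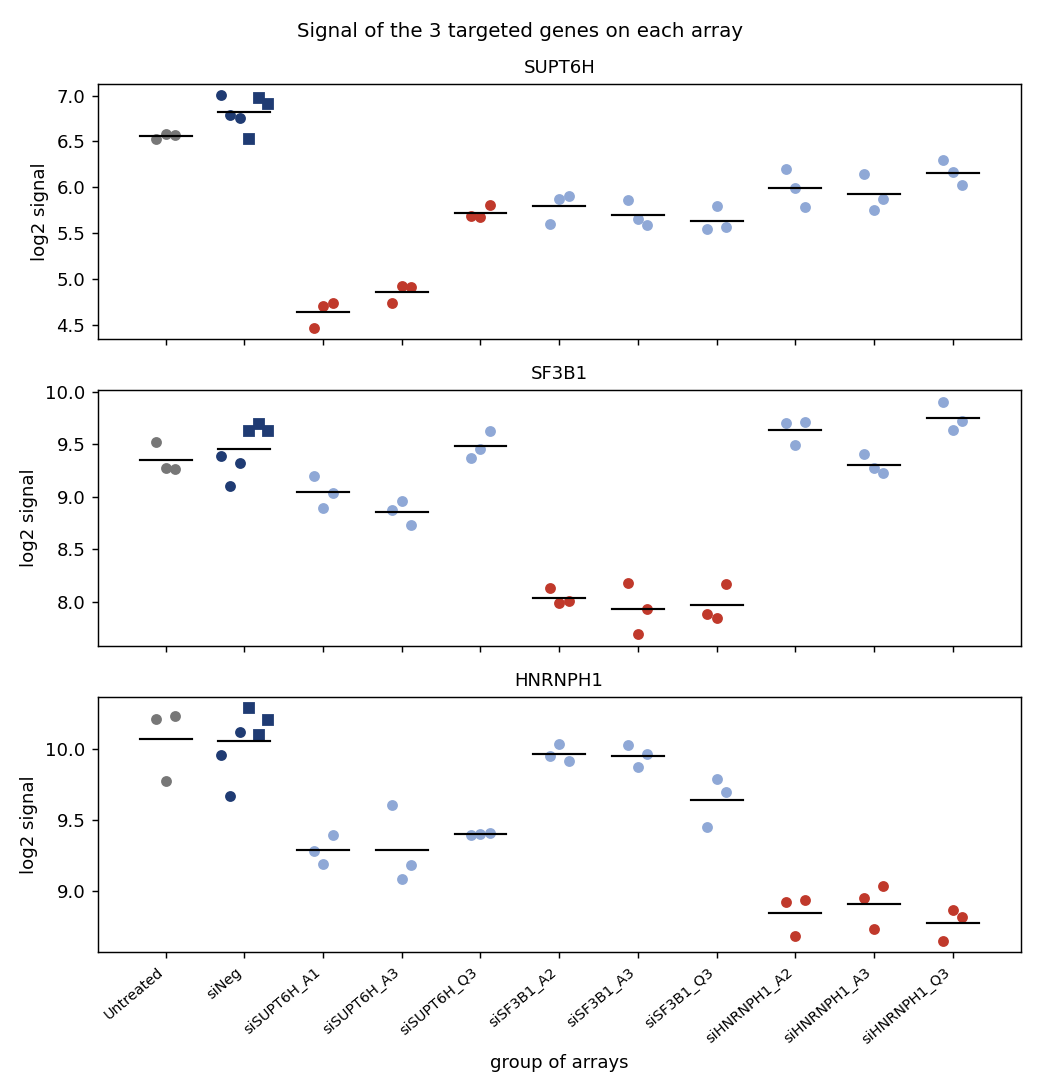
Normalized log2 signal of SUPT6H, SF3B1 and HNRNPH1 (y axis) on each of 36 arrays in 11 groups (x axis), with red points for siRNAs against that gene, dark blue for siNeg (squares for set 2), grey for Untreated, light blue for the other siRNAs and a bar at each group mean. The red points averaged -1.75, -1.48 and -1.21 below siNeg.

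The next question was which transcripts followed the loss of SUPT6H. The genes of the integrated stress response, which the transcription factor ATF4 drives, fell furthest: TRIB3 (-4.19, SE 0.09, adjusted p = 3.29e-31), DDIT3 (-3.91, SE 0.08, adjusted p = 4.87e-32), PCK2 (-3.88), whose enzyme works in mitochondria, and the asparagine synthetase gene ASNS (-3.57, SE 0.07, adjusted p = 2.73e-32), with 9 arrays against 6 throughout. The chaperone HSPA1A rose by 3.62 (SE 0.21, adjusted p = 2.14e-17; own-run 2.75), with a wide spread among siNeg arrays (SD 0.97). The muscle ubiquitin ligase TRIM55 rose by 3.55 (SE 0.09, adjusted p = 2.48e-28) and the histone gene H2BC5 by 3.16 (SE 0.09, adjusted p = 2.07e-27). Other large rises were SNORA12 (3.13), VASN (3.07), ANGPTL4 (2.52, its probes spanning 0.09 to 2.52), ATP2B1-AS1 (2.51), CD248 (2.44), H2AC6 (2.29) and the Cajal body RNAs SCARNA18 (2.42) and SCARNA16 (2.36). ZCCHC12 was detected on 0 of 6 siNeg arrays and rose at least 4.3-fold (adjusted p = 3.59e-23). NUPR1 (-3.64), ATF5 (-3.46), BEX2 (-3.19), RPS6KA2 (-2.94, detected on 4 of 9 siSUPT6H arrays) and AKNA (-2.93, 8 of 9) fell, and 3 genes dropped out of detection: GDF15 at least 9.67-fold (adjusted p = 1.07e-23), LGALS7B at least 4.83-fold (adjusted p = 1.33e-23) and S100P at least 4.72-fold (adjusted p = 6.16e-25). All of these had been picked from the genes called in the same direction with each of the 3 siRNAs.

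In all, 6551 of 11437 genes were called with siSUPT6H (3217 higher, 3334 lower), and 3181 (1490 higher, 1691 lower) were called in the same direction with each siRNA. Own-run values gave 5424 (2934 higher, 2490 lower) and 2699, and 4651 and 2222 genes were called the same way in both. With siRNA and siNeg set as a random block (correlation 0.511) 3293 genes were called, and 2450 with siRNA means as replicates. EWSR1, the 5' partner of the fusion oncogene of Ewing sarcoma, fell by 0.46 (adjusted p = 5.15e-06; own-run -0.44). FLI1, the 3' partner, was called higher against all 6 siNeg arrays (0.59, adjusted p = 0.00276) but stood at -0.01 in own-run values (adjusted p = 0.956), so no direction is given for it. Whether these probes also read the fusion transcript is not told by the annotation. HNRNPH2 (0.13, adjusted p = 0.204) was called in own-run values (0.31, adjusted p = 0.00566), in the authors' values (0.27, adjusted p = 0.00337) and against Untreated (0.36, adjusted p = 0.00138). Its other probe gave 0.79. HNRNPF (0.03) and SUPT5H (0.01) were not called, but were against Untreated (-0.29, adjusted p = 0.0257, and 0.26, adjusted p = 0.0197).

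Among fixed gene lists, the G2/M and mitosis genes fell with siSUPT6H: 38 of 45 fell, 0 rose and 7 were not called (39 fell when adjusted over the list alone; median -0.70, adjusted p = 7.51e-16), among them KIF2C (-1.69), TPX2 (-1.64), CENPA (-1.54) and TOP2A (-1.45). Of 35 integrated stress and unfolded protein response genes 26 fell, 5 rose and 4 were not called (median -1.63, adjusted p = 1.89e-15). Heat shock genes rose (18 of 25, with 1 lower and 6 not called, median 0.46, adjusted p = 1.86e-05), for example HSPA1B (2.06) and DNAJB4 (1.17). Histone genes rose as well (12 of 23, with 1 lower and 10 not called, median 0.23, adjusted p = 0.00104), H2AC18 by 1.42 and H2BC12 by 1.30. So did cholesterol synthesis genes (10 of 21, with 2 lower and 9 not called, median 0.18, adjusted p = 0.0249), MSMO1 by 1.17, IDI1 by 1.12 and DHCR7 by 0.98. These 5 calls held with an estimated correlation between genes. Lost with it was the fall of DNA replication and G1/S genes (37 of 46 lower, 3 higher, 6 not called, or 39 and 3 over the list alone; median -0.54, adjusted p = 4.43e-08, adjusted p = 0.0548 with an estimated correlation; PRIM1 -1.43, RFC4 -1.14, MCM2 -1.03). The fall of nonsense-mediated decay factors was lost too (11 of 15 lower, 2 higher, 2 not called, median -0.37, adjusted p = 0.0276, adjusted p = 0.392 with an estimated correlation, own-run adjusted p = 0.135, adjusted p = 0.179 in the authors' values and 0.224 against Untreated; SMG5 -0.93, CASC3 -0.87, SMG9 -0.76). Also lost was the rise of SR proteins and SR kinases (16 of 24 higher, 3 lower, 5 not called, median 0.24, adjusted p = 0.0276, adjusted p = 0.123 with an estimated correlation; median 0.17, adjusted p = 0.122, against set 2 and 0.06, adjusted p = 0.538, against Untreated; CLK4 0.81, SRSF11 0.71, SRPK2 0.64, SRSF8 0.61).

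Lists not called with siSUPT6H still held large single changes. Of 35 EWS-FLI1 activated targets 12 rose, 14 fell and 9 were not called (adjusted p = 0.831), with LIPI at 1.5, AURKA at -1.42 and AURKB at -1.36. Of 28 EWS-FLI1 repressed targets 13 rose, 8 fell (10 over the list alone) and 7 were not called (adjusted p = 0.854), the median at -0.06 but the mean at 0.02. The hnRNP genes (5 higher, 16 lower and 7 not called of 28, median -0.24, adjusted p = 0.0552) were called lower in own-run values (adjusted p = 0.0136), in the authors' values (adjusted p = 0.0116), without background correction (adjusted p = 0.0415) and against Untreated (adjusted p = 0.0323). TAF15 stood at -1.19. Other core spliceosome components (6 higher, 24 lower and 15 not called of 45, or 7 and 24 over the list alone, median -0.21) had an adjusted p of 0.064, with PRPF3 at -1.45. They were called lower without background correction (adjusted p = 0.0401) and in the authors' values (adjusted p = 0.0355). Neuronal differentiation genes (3 higher, 10 lower and 9 not called of 22, adjusted p = 0.116) included SCG2 (-1.91) and GAP43 (-1.26). The p53 target genes split 10 higher, 8 lower and 9 not called of 27 (11 and 9 over the list alone, adjusted p = 0.718), with CDKN1A at 1.90 and SESN2 at -1.64. Immediate early genes split 17 higher, 9 lower and 10 not called of 36 (adjusted p = 0.718), with ATF3 at -2.54 and KLF4 at -1.58.

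For SF3B1 the question was the same, and small nucleolar RNA genes led the rises. SNORA63 rose by 3.42 (SE 0.10, adjusted p = 4.57e-27), SNORD55 by 3.20, SNORD25 by 3.10, SNORA68 by 3.03, SNORA6 by 3.01, SNORD99 by 2.84, SNORD36A by 2.68 (own-run 2.09) and SNORA28 by 2.63 (9 arrays against 6). Some were dim in siNeg: of its 6 arrays 3 detected SNORA63, 5 SNORD55, 4 SNORD25, 2 SNORA68, 4 SNORD99 and 1 SNORA28. SNHG17, which hosts a snoRNA gene, rose by 2.74, SCARNA18 by 2.73 and RSRP1 by 2.94, the last on 1 probe only (the other gave -0.20). BEGAIN, below detection in siNeg, rose at least 5.68-fold (adjusted p = 1.36e-24). The stress response genes fell again: ATF5 (-3.88, SE 0.11, adjusted p = 3.83e-27), PCK2 (-3.85, SE 0.11, adjusted p = 1.84e-27), GDF15 (-3.44, detected on 2 of 9 siSF3B1 arrays), ASNS (-3.42, SE 0.07, adjusted p = 1.41e-31), the cystathionine gamma-lyase gene CTH (-3.22) and NUPR1 (-3.11). Lower too were the chemokine CXCL14 (-3.10, own-run -2.47), BEX2 (-2.98) and CACNG3 (-2.74, 1 of 9 arrays). RPS6KA2 at least 6.98-fold (adjusted p = 3.26e-24), ULBP1 at least 5.15-fold (adjusted p = 1.92e-22) and S100P at least 3.96-fold (adjusted p = 1.06e-24) fell below detection.

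With siSF3B1, 7950 genes were called (3222 higher, 4728 lower) and 5414 with each siRNA in the same direction (2085 higher, 3329 lower). The siSF3B1 arrays detected fewer probes (13106 to 14853) than the siNeg arrays (15319 to 16295). The median change of all genes was -0.093, and 40.5% of the called genes were higher. Whether the lower detection bears on this excess of lower genes was not tested. Own-run values called 7082 and 4891, of which 6417 and 4346 were called the same way in both. The random block called 5353 and siRNA means as replicates 4924. EWSR1 fell by 1.06 (SE 0.08, adjusted p = 1.12e-14; own-run -1.04) while FLI1 rose by 1.58 (adjusted p = 1.21e-10; own-run 0.98). HNRNPF (0.34) and SUPT5H (-0.36) were called against all siNeg arrays but not in own-run values (0.17, adjusted p = 0.169, and -0.17, adjusted p = 0.117), and HNRNPH2 was not called (-0.11, adjusted p = 0.249). Against siNeg set 2 HNRNPH2 was called (-0.29, adjusted p = 0.00559), while its other probe gave 0.75.

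The siSF3B1 arrays shifted 4 lists. SR proteins and SR kinases rose (19 of 24, with 3 lower and 2 not called, 19 and 4 over the list alone; median 0.67, adjusted p = 1.47e-05), led by SRSF11 (2.45), SRRM1 (1.80), PRP4K (1.42) and TRA2B (1.36). Heat shock genes rose (20 of 25, with 3 lower and 2 not called, median 0.60, adjusted p = 8.63e-06), including HSPA4 (2.29, own-run 1.32), HSPA1A (2.00, own-run 1.12) and CHORDC1 (1.49), while HSPA9 fell by 1.70. Those 2 calls held with an estimated correlation. The fall of integrated stress and unfolded protein response genes (26 of 35 lower, 8 higher, 1 not called, or 27 and 8 over the list alone; median -0.99, adjusted p = 5.47e-05) was lost with it (adjusted p = 0.0894 with an estimated correlation), although DDIT4 alone fell by 2.72. The rise of immediate early genes (21 of 36 higher, 9 lower, 6 not called, median 0.39, adjusted p = 0.0104) was lost too (adjusted p = 0.0517 with an estimated correlation); NR4A2 rose at least 2.16-fold (adjusted p = 3.94e-15) and RHOB by 1.27, against KLF4 at -1.80 and ATF3 at -1.47.

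Histone genes were not called with siSF3B1 (13 higher, 4 lower and 6 not called of 23, adjusted p = 0.0655), although their median of 0.26 was no smaller than with siSUPT6H. Of the remaining lists, the U2 snRNP and SF3B components (8 higher, 5 lower and 8 not called of 21, median 0.06, adjusted p = 0.115) were called higher in own-run values (adjusted p = 0.0287), in the authors' values (adjusted p = 0.0214) and against Untreated (adjusted p = 0.0139). SMNDC1 (1.58), DDX46 (1.48) and SF3B4 (1.15) rose. Other core spliceosome components split 21 higher, 13 lower and 11 not called of 45 (22 and 13 over the list alone, adjusted p = 0.186), with CDC5L at 1.51 and PLRG1 at -1.47. They were called higher against Untreated (adjusted p = 0.0235). Among hnRNP genes (12 higher, 10 lower and 6 not called of 28, adjusted p = 0.398) PTBP2 rose by 1.79 and TAF15 fell by 1.30. Cholesterol synthesis genes (11 higher, 6 lower and 4 not called of 21, median 0.19, adjusted p = 0.0655) included MSMO1 (2.51) and HMGCS1 (1.64). They were called higher in the authors' values (adjusted p = 0.0424) and against Untreated (adjusted p = 0.0117). G2/M and mitosis genes, in contrast to siSUPT6H, split 19 higher, 13 lower and 13 not called of 45 (20 and 13 over the list alone, adjusted p = 0.14), with KPNA2 at 1.53 and TOP2A at -1.36. EWS-FLI1 activated targets split 12 higher, 11 lower and 12 not called of 35 (11 and 11 over the list alone, median 0.04 but mean -0.04, adjusted p = 0.718; PHF19 -1.86), and repressed targets 6 higher, 15 lower and 7 not called of 28 (adjusted p = 0.207; PHLDA1 -1.87, IGFBP3 -1.84).

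With siHNRNPH1 the largest rises included matrix and mesenchymal genes, beside TRIM55 and VASN, which were also among the largest rises with siSUPT6H. The matrix Gla protein MGP rose by 4.54 (SE 0.07, adjusted p = 2.5e-35) and IGFBP3 by 4.15 (SE 0.10, adjusted p = 3.09e-30). By siRNA, MGP rose by 5.28 (A2), 5.19 (A3) and 3.16 (Q3), a spread that its SE leaves out. The retinoic acid binding protein CRABP2 rose by 3.91, TRIM55 by 3.83 and the collagen COL1A1 by 3.77 (SE 0.10, adjusted p = 8.32e-29, 9 arrays against 6). SPRY1 (3.56), IER3 (3.50), PRRX1 (3.46, detected on 2 of 6 siNeg arrays), VASN (3.43), the chemokine CCL2 (3.38) and TGM2 (3.38, 1 of 6 siNeg arrays, its probes spanning 0.75 to 3.38) rose too. COLEC12, below detection in siNeg, rose at least 7.98-fold (adjusted p = 5.11e-30). The falls were again of stress response genes: CTH (-3.83, SE 0.12, adjusted p = 1.97e-26), PCK2 (-3.51), TRIB3 (-3.42), ASNS (-3.23), ATF5 (-3.20), DDIT3 (-2.74) and SLC6A9 (-2.23). AKNA (-2.79), S100P (-2.72, 1 of 9 siHNRNPH1 arrays) and BEX2 (-2.29) also fell, and ULBP1 (at least 5.63-fold, adjusted p = 1.53e-22) and CHAC1 (at least 3.64-fold, adjusted p = 6.65e-23) fell below detection.

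With siHNRNPH1, 6187 genes were called (3265 higher, 2922 lower), of which 2579 with each siRNA in the same direction (1409 higher, 1170 lower). Own-run values gave 5160 and 2221, and 4277 and 1709 were called the same way in both. The random block called 2790 and siRNA means as replicates 1895. EWSR1 changed little (-0.18, adjusted p = 0.0494; own-run -0.20, adjusted p = 0.0779) and its call was lost on leaving out any of 27 arrays. FLI1 was lower against all siNeg arrays (-0.92, adjusted p = 1.66e-05, detected on 4 of 9 siHNRNPH1 arrays) but not called in own-run values (-0.31, adjusted p = 0.0521) or in the authors' values (-0.08, adjusted p = 0.374). SUPT5H rose by 0.61 (own-run 0.42). HNRNPH2, the closest relative of HNRNPH1, was called at 0.27 but not in own-run values (0.09, adjusted p = 0.454), and its other probe gave -0.37. HNRNPF was not called (-0.03), but was against Untreated (-0.35, adjusted p = 0.00566).

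EWS-FLI1 repressed targets rose with siHNRNPH1: 21 of 28, with 3 lower and 4 not called (median 1.43, adjusted p = 8.11e-15), DKK1 by 3.21 beside IGFBP3, SPRY1 and IER3. Extracellular matrix and mesenchymal genes rose (26 of 36, with 1 lower and 9 not called, median 0.69, adjusted p = 3.27e-12), including TAGLN (2.61), COL5A1 (2.59) and SNAI2 (2.30). TAGLN and COL5A1 are also on the list of EWS-FLI1 repressed targets, as is CCN1 of the immediate early genes. The calls of these lists therefore rest in part on the same genes. Histone genes rose (14 of 23, with 1 lower and 8 not called, median 0.38, adjusted p = 0.000108), H2BC5 by 2.81, H2BC12 by 1.84 and H2AC6 by 1.62. G2/M and mitosis genes fell (34 of 45, with 1 higher and 10 not called, median -0.51, adjusted p = 1.4e-09), with NEK2 at -1.53 and NDC80 at -1.10 (in the authors' values -0.13, adjusted p = 0.0793). Integrated stress and unfolded protein response genes fell too (28 of 35, with 5 higher and 2 not called, median -1.23, adjusted p = 1.89e-15). These 5 calls held with an estimated correlation. Another 3 calls were lost with it. EWS-FLI1 activated targets fell (21 of 35 lower, 4 higher, 10 not called, or 22 and 4 over the list alone; median -0.26, adjusted p = 0.00139, adjusted p = 0.11 with an estimated correlation), with EZH2 at -1.39, TNFAIP6 at -1.04 and HOXD13 at -1.01 but PHF19 at 1.24. Other core spliceosome components fell (19 of 45 lower, 6 higher, 20 not called, median -0.13, adjusted p = 0.023, adjusted p = 0.0961 with an estimated correlation; PLRG1 -0.81). They had a median of -0.04 against set 1 (adjusted p = 0.0959) and of 0.03 against Untreated (adjusted p = 0.252). Immediate early genes rose (18 of 36 higher, 6 lower, 12 not called, median 0.29, adjusted p = 0.0146, adjusted p = 0.0556 with an estimated correlation, adjusted p = 0.0972 against set 1), with ZFP36L2 at 2.21, CCN1 at 1.86 and NFKBIA at 1.78.

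Heat shock genes (13 higher, 3 lower and 9 not called of 25, or 14 and 3 over the list alone; median 0.28, adjusted p = 0.0849; CRYAB 2.12) and cholesterol synthesis genes (10 higher, 3 lower and 8 not called of 21, median 0.18, adjusted p = 0.0655) were not called with siHNRNPH1 against all 6 siNeg arrays, but were in own-run values (adjusted p = 0.0225 and 0.0116) and in the authors' values (adjusted p = 0.0168 and 0.00563). Interferon response genes had 16 higher, 5 lower and 12 not called of 33 (17 and 5 over the list alone, median 0.27, adjusted p = 0.0549), with IFI6 at 1.42 and IRF1 at 1.04. They were called higher without background correction (adjusted p = 0.0467). CDKN1A rose by 2.31 while p53 target genes split 9 higher, 8 lower and 10 not called of 27 (adjusted p = 0.751). SR proteins and SR kinases had 12 higher, 5 lower and 7 not called of 24 (adjusted p = 0.398; SRPK2 1.07), and hnRNP genes 10 higher, 9 lower and 9 not called of 28 (adjusted p = 0.961; HNRNPA1 0.94).

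Several lists were called with none of the 3 targets, as counts in the order siSUPT6H, siSF3B1, siHNRNPH1. Transcription elongation factors (41 measured) had 12, 18 and 14 higher and 9, 16 and 7 lower (adjusted p = 0.718, 0.482 and 0.647), with TCEA1 at -1.62 with siSUPT6H and -1.66 with siHNRNPH1 and TCEA2 at -2.03 with siSF3B1. BCL2 family genes (16) had 5, 5 and 7 higher and 5, 7 and 5 lower (adjusted p = 0.864, 0.854 and 0.97), BCL2L2 at -1.34 with siSUPT6H and PMAIP1 at -1.87 with siHNRNPH1. Ribosomal protein genes (67) had 9, 13 and 12 higher and 14, 16 and 6 lower (adjusted p = 0.872, 0.718 and 0.834; over the list alone 12 higher and 13 lower with siSF3B1, 12 and 4 with siHNRNPH1), RPL34 at 1.37 and RPS7 at -1.31 with siSUPT6H. Intronless genes (42) had 17, 14 and 16 higher and 12, 16 and 12 lower (adjusted p = 0.675, 0.834 and 0.498; over the list alone 17 and 13 with siSUPT6H, 15 and 18 with siSF3B1), IRX3 at 1.67 with siHNRNPH1. Epithelial markers (6) had 1, 4 and 1 higher and 1, 2 and 1 lower (adjusted p = 0.883, 0.577 and 0.966). Blood cell markers (6) had 4 higher and 1 lower each time (adjusted p = 0.498, 0.14 and 0.293), and 0 of 15 skeletal muscle markers were measured.

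**Figure D2:**
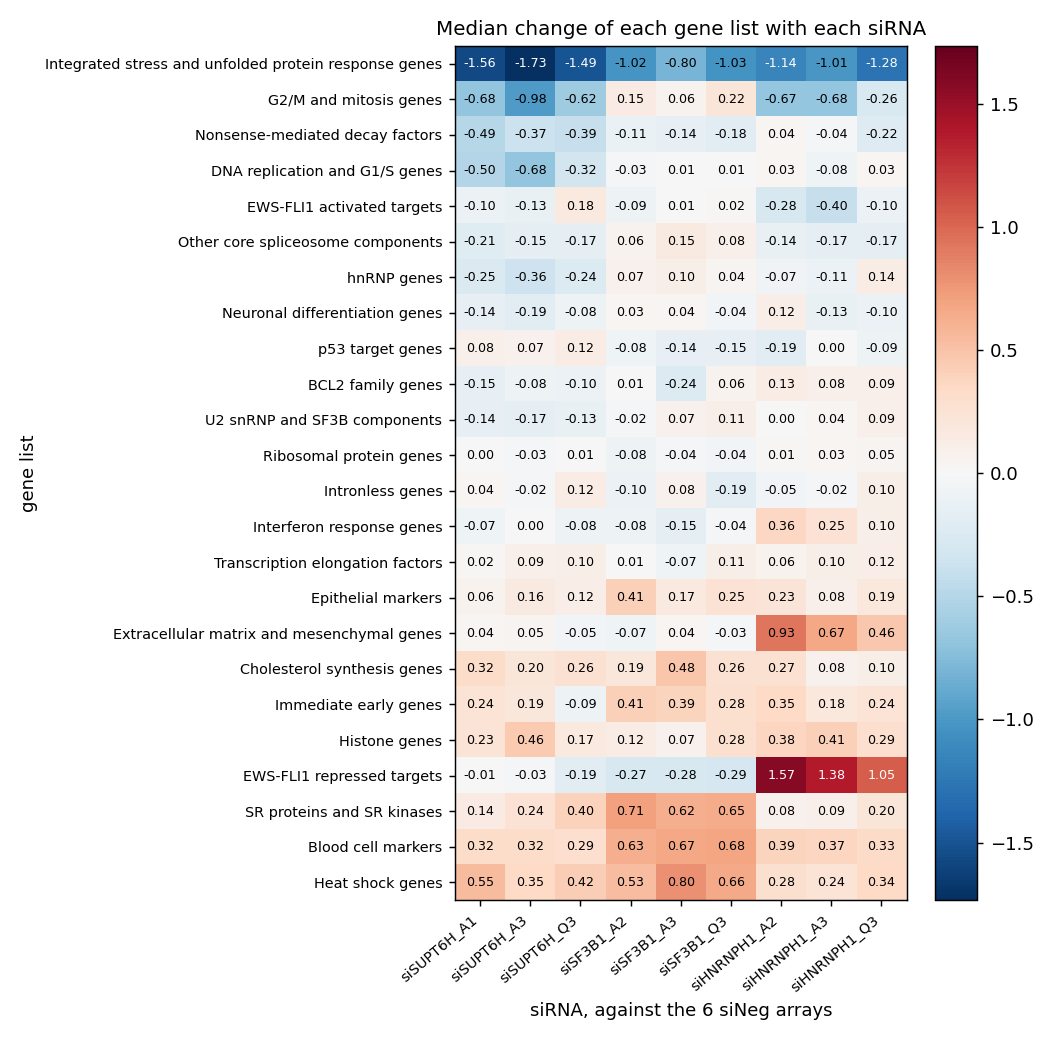
Heat map of the median log2 change of 24 gene lists (y axis) with each of 9 siRNAs against the 6 siNeg arrays (x axis), red higher and blue lower. Integrated stress response genes were lower in every column, with medians over each target of -1.63, -0.99 (call lost with an estimated correlation, adjusted p = 0.0894) and -1.23, and EWS-FLI1 repressed targets were higher with siHNRNPH1 (1.43).

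Whether the changes differed between targets was tested directly. Between siSUPT6H and siSF3B1 8025 genes differed (4710 higher with siSUPT6H): TRIM55 by 4.59 (detected on 1 of 9 siSF3B1 arrays), IDNK by 3.67, CCDC3 by 3.13 and H2BC5 by 2.92, against SNHG1 (-3.69), SNHG17 (-3.39), SNORA68 (-3.28) and SNORD25 (-3.24). SNHG1, a host of snoRNA genes, changed by -1.81 with siSUPT6H and 1.89 with siSF3B1. Between siSUPT6H and siHNRNPH1 7671 differed (3357 higher; own-run 3462 in all), with IGFBP3 at -5.32, DKK1 at -4.60, CCL2 at -4.24 and MGP at -4.20 (own-run -5.10, -4.89, -4.10 and -3.95) and POU4F1 at 2.57 (own-run 2.21). HSPA1A (3.78), TRMT10C (2.77) and PTMA (2.86) stood at 2.03, 0.78 and 0.07 in own-run values. Between siSF3B1 and siHNRNPH1 8777 differed (3471 higher; own-run 5998 in all), with IGFBP3 at -5.99, MGP at -5.39, TRIM55 at -4.87 and CCDC3 at -4.83, and RSRP1 at 3.29, SNORD25 at 3.21, LUC7L3 at 3.25 (own-run 1.49) and PTMA at 3.39 (own-run 0.60). G2/M and mitosis genes were lower with siSUPT6H than with siSF3B1 (median difference -0.94, adjusted p = 8.48e-18) or siHNRNPH1 (-0.41, adjusted p = 2.24e-09). EWS-FLI1 repressed targets were lower with siSUPT6H (-0.74, adjusted p = 1.86e-16) and siSF3B1 (-1.36, adjusted p = 7.56e-12) than with siHNRNPH1, and extracellular matrix genes likewise (-0.50, adjusted p = 2.55e-12, and -0.65, adjusted p = 8.16e-07). SR proteins and SR kinases were lower with siSUPT6H than with siSF3B1 (-0.48, adjusted p = 0.00799) and higher with siSF3B1 than with siHNRNPH1 (0.47, adjusted p = 3.84e-05). These list differences held with an estimated correlation.

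The 3 siRNAs of a target were also compared with each other, in the order A1, A3, Q3 for SUPT6H and A2, A3, Q3 for the others. Among siSUPT6H siRNAs 3023 genes differed, for example LAMA4 (1.90, 1.87 and -0.68 against siNeg), PRND (2.19, 2.92 and -0.25), MAP3K7CL (1.63, 2.04 and -0.37), HSPH1 (0.62, -0.95 and 1.32), IGFBP2 (-0.22, 0.00 and -1.70) and CCDC86 (0.21, 0.20 and -1.48). Fewer, 880, differed among siSF3B1 siRNAs (487, 512 or 534 without A3 replicate 1, 2 or 3), with A3 apart at COL3A1 (-1.96, -0.59 and -1.93), POLE3 (-0.93, 0.47 and -0.97), CYYR1 (-0.43, 1.21 and -0.45), SDC2 (-0.77, 0.62 and -0.68), IRAK1 (-1.96, -0.69 and -1.87) and DDX47 (-0.10, 0.87 and -0.05). Among siHNRNPH1 siRNAs 3824 differed, including VGF (2.32, 3.74 and -0.62), H19 (0.75, 3.23 and 1.19), SCARNA13 (3.41, 0.88 and 3.22), FGFBP2 (2.25, 0.24 and 0.08), MGP (5.28, 5.19 and 3.16) and MMP11 (3.08, 3.19 and 0.13).

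A further question was what the 9 siRNAs had in common. With all of them 545 genes were called in the same direction (173 higher, 372 lower) against the shared siNeg arrays. With separate control arrays for each target (set 1 for siSUPT6H, Untreated for siSF3B1, set 2 for siHNRNPH1) 466 were, where independent lists of the same sizes would share 22.3 higher and 32.9 lower. Simulated unchanged groups set against the same 6 siNeg arrays shared 0 in each of 50 draws with limma. These groups were drawn around the mean of those same arrays, so they could not show how much overlap shared control arrays add. Set against the siNeg arrays of the own run instead, the same groups shared a median of 283 genes between siSUPT6H and siSF3B1, and 0 over all 9 siRNAs. Those 283 hold the difference between the siNeg sets, because the groups were drawn around the mean of both sets. Groups drawn around the siNeg mean of their own run shared 0 in own-run values, which again could not show the overlap that shared control arrays add. PCK2 fell with every siRNA (mean -3.75, single siRNAs -3.94 to -3.43). Its 3 probes disagreed in size, spanning -3.88 to -1.17 with siSUPT6H, -3.85 to -1.11 with siSF3B1 and -3.51 to -1.06 with siHNRNPH1. Falls with every siRNA were also seen for ASNS (mean -3.40, -3.60 to -3.13), ATF5 (-3.51), TRIB3 (-3.37), CTH (-3.23), GDF15 (-3.06, detected on 9 of 27 arrays), NUPR1 (-2.83) and BEX2 (-2.82). VASN rose with each (mean 2.71, 1.27 to 3.75), as did SCARNA18 (2.69), SNORA12 (2.48), SCARNA16 (2.33), SNORA79 (2.15, 1 of 6 siNeg arrays), SCARNA13 (1.97), TENT5A (1.92) and SCARNA8 (at least 3.07-fold on average, 0 of 6 siNeg arrays, largest adjusted p = 0.0012). Some of these had fallen in siNeg against Untreated: SCARNA18 (-0.88, adjusted p = 0.000181), SNORA79 (-0.64, adjusted p = 0.0213), SNORA12 (-0.40, adjusted p = 0.0366) and VASN (-0.39, adjusted p = 0.0476). Against Untreated their means were 1.81, 1.5, 2.08 and 2.32. Of the falls, GDF15 (1.14), NUPR1 (0.60) and TRIB3 (0.52) were called higher in siNeg, and against Untreated their means were -1.92, -2.23 and -2.85. By pairs of targets, 592 genes rose, 998 fell and 346 went opposite ways with siSUPT6H and siSF3B1 against the shared siNeg arrays, with 430, 514 and 129 for siSUPT6H and siHNRNPH1. The numbers were 350, 592 and 484 for siSF3B1 and siHNRNPH1. With separate control arrays they were, in the same order, 396, 657 and 423 (236.9, 329.3 and 578.3 for independent lists), 410, 555 and 46 (133.7, 128 and 262.4) and 238, 604 and 301 (180.4, 293.4 and 468.1).

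Last, siNeg was compared with Untreated cells. The glucose transporter SLC2A3 rose by 1.76 (SE 0.11, adjusted p = 1.37e-14, 6 arrays against 3; own-run 1.65), IGFBP3 by 1.24 (own-run 1.13, its probes spanning 0.71 to 1.24), GDF15 by 1.14 (own-run 1.12) and SLC33A2 by 1.05 (own-run 0.73). MMP10 (1.04), TNFRSF21 (0.97), SNHG7 (0.94, its probes spanning 0.08 to 0.94) and the aldo-keto reductases AKR1C3 (0.98), AKR1C2 (0.96) and AKR1C4 (0.94) rose too. PRSS35 fell by 1.33 (SE 0.12, adjusted p = 4.01e-10; own-run -1.43), as did GOLT1B (-1.41, own-run -1.02), DTL (-1.32, own-run -0.78), NUCB2 (-1.39, own-run -0.67), NAA50 (-1.37, 4 of 6 siNeg arrays, own-run -0.67), the replication clamp gene PCNA (-1.42, own-run -0.60, its probes spanning -1.42 to -0.04) and HSPA1A (-1.46, SE 0.28, adjusted p = 0.000483, own-run -0.59). PTGES3 (-1.35), SAP30 (-1.28) and PTMA (-1.30, adjusted p = 0.0303) were called against all siNeg arrays but not in own-run values (-0.29, adjusted p = 0.252; -0.30, adjusted p = 0.126; 0.10, adjusted p = 0.778), nor was FLI1 (-0.82, adjusted p = 0.0119; own-run -0.22, adjusted p = 0.502). SUPT6H (0.27, adjusted p = 0.132), SF3B1 (0.11, adjusted p = 0.574) and HNRNPH1 (-0.02, adjusted p = 0.946) were not called.

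Between siNeg and Untreated 1745 genes were called (879 higher, 866 lower, 50.4% higher), but 849 with set 1 alone (305 higher, 544 lower, 35.9% higher). In the authors' values 39% were higher, and 568 were called the same way with both controls. Leaving out 1 Untreated array moved 1745 to 1135 (replicate 1), 951 (replicate 2) or 967 (replicate 3). DNA replication and G1/S genes fell (16 of 46 lower, 0 higher, 30 not called, or 20 and 0 over the list alone; median -0.24, adjusted p = 3.51e-08, adjusted p = 0.0546 with an estimated correlation), with MCM10 at -1.07, TK1 at -0.68 and RFC5 at -0.66. Heat shock genes fell (6 of 25 lower, 1 higher, 18 not called, or 7 and 1 over the list alone; median -0.20, adjusted p = 0.00427), a call that held with an estimated correlation. Integrated stress and unfolded protein response genes rose (10 of 35 higher, 1 lower, 24 not called, or 11 and 1 over the list alone; median 0.20, adjusted p = 0.00458, adjusted p = 0.218 with an estimated correlation, own-run adjusted p = 0.0501), with SESN2 at 0.84, ATF3 at 0.76 and STC2 at 0.74. SR proteins and SR kinases were not called against all siNeg arrays (median -0.14, adjusted p = 0.0528) but were lower in own-run values (adjusted p = 0.00441), in the authors' values (adjusted p = 0.00142) and without background correction (adjusted p = 0.0315). Cholesterol synthesis genes (median 0.13, adjusted p = 0.115) were called higher in own-run values (adjusted p = 0.0206) and in the authors' values (adjusted p = 0.0214). No other list was called by camera with all 6 siNeg arrays or in own-run values.

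The siNeg sets themselves differed at 4165 genes (2755 higher and 1410 lower in set 2, 3 arrays against 3), 1252 of them by at least 1.5-fold. RPL21P28 stood at -3.09 in set 2 (SE 0.14, adjusted p = 6.61e-24), the chromatin-associated PTMA at -2.79 (adjusted p = 1.99e-22), RPL23AP87 at -2.62 and the chaperonin subunit TCP1 at -2.48, while VEGFA (1.33), CXCL14 (1.27), ASF1B (1.23) and RCOR2 (1.16) were higher. This difference enters every comparison with all 6 siNeg arrays, and is why own-run values stand beside the main ones.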

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

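The tests of the control sets, of the siNeg and run explanations for the stress response genes, and all splits of the arrays were chosen only after the results had been seen; the matched-list test of the stress response genes was fixed before its values were computed.

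The siNeg arrays of set 2 differed from those of set 1 at 4165 genes, and PTMA was lower in set 2 by a log2 change of -2.79. The authors' normalization in separate runs is excluded as the whole cause, because the 4165 genes were called in signals that had been normalized here in one go. A shift of the 3 set 2 arrays alone is excluded too: siHNRNPH1 arrays, set against Untreated, siSUPT6H or siSF3B1 arrays, followed the set difference across genes with slopes of 0.78 to 0.97. The shift therefore belonged to the whole of run 2. Whether labelling and hybridisation of run 2 as against culture and transfection of run 2 caused it cannot be told apart, since 0 groups other than siNeg had arrays in both runs, and until then own-run values are the safer ones for siHNRNPH1.

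Integrated stress response genes were lower with all 9 siRNAs, with list medians of -1.63, -0.99 and -1.23 over the 3 targets and PCK2, ASNS and ATF5 among the largest falls; the list call for siSF3B1 was lost with an estimated correlation (adjusted p = 0.0894). That siNeg raised these genes is excluded as the only cause: against Untreated arrays the 9 medians ran from -1.46 to -0.59, while siNeg itself stood at 0.08 (set 1) and 0.26 (set 2). The difference between the runs is excluded as well, with own-run medians of -1.58 to -0.78. A fall of all mRNAs of the same level is excluded, the lowest median of 10000 random lists of the same size and mean level being -0.60. Whether losing any of the 3 proteins or carrying an active siRNA lowered these genes was not separated, because siNeg was the only siRNA without one of these targets, and the activity of ATF4 was not measured.

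Splits of the arrays into other groups of the same sizes were used to ask whether chance could give as many calls by limma. Counting the real one, 1 of 100 splits gave as many genes for siSUPT6H (6551, highest other 3515), siSF3B1 (7950, highest other 6470) and siHNRNPH1 (6187, highest other 4691). A chance assignment of single arrays is excluded there. It is excluded in the same way, at 1 of 100, for genes called with all 3 siRNAs (3181 against 31, 5414 against 1342 and 2579 against 958), for own-run values (5424 against 2843, 7082 against 3765 and 5160 against 2902), for differences between targets (8025 against 6654, 7671 against 3586 and 8777 against 4202), for differences among siRNAs (3023 against 2391, 880 against 758 and 3824 against 2400) and for all 9 siRNAs (545 against 0). Other splits mixed arrays of different groups, which widens the spread within groups, and whole siRNAs were not exchanged. The splits cannot tell targets from runs where siHNRNPH1 is compared with siSUPT6H or siSF3B1 (own-run 3462 and 5998 genes). The number of lists called within a comparison, adjusted in that comparison alone, excluded a chance assignment of single arrays for siSUPT6H (1 of 100 splits, 10 against 9) and siHNRNPH1 (3 of 100 splits, 10 against 10). It did not for siSF3B1 (26 of 100 splits, 4 against 5) or for siNeg against Untreated (7 of 84 splits, 3 against 5). For genes between siNeg and Untreated 2 of 84 splits reached the real 1745, the other one, with 4774, setting apart the 3 set 2 arrays. Between the siNeg sets there were too few splits, 10, to exclude chance (4165 against 3).

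Other results stood out by rules fixed beforehand. Among the 3 siSUPT6H siRNAs 3023 genes differed, SUPT6H itself with an adjusted p of 2.32e-07, with 46.7% of its mRNA left by Q3 and at most 26.1% by A1. Among siSF3B1 siRNAs 880 differed, or 487, 512 or 534 without A3 replicate 1, 2 or 3, and among siHNRNPH1 siRNAs 3824. Between targets 8025 genes (siSUPT6H and siSF3B1), 7671 (siSUPT6H and siHNRNPH1, 3462 in own-run values) and 8777 (siSF3B1 and siHNRNPH1, 5998 in own-run values) differed. These counts rest on the spread of arrays within a siRNA. Targets were not compared with siRNAs as replicates, so differences among single siRNAs can enter them. EWSR1 in siNeg replicate 4 stood apart, at 10.17 against 10.01 for the next array (a gap of 0.763 of the range), the only one of 10 quantities examined, and chance sets an array apart in about 1 in 20 groups. Of 4527 kept probes without exactly 1 gene symbol, 684 were called with all 3 siSUPT6H siRNAs (348 higher, 336 lower), 1503 with siSF3B1 (1012 higher, 491 lower) and 528 with siHNRNPH1 (195 higher, 333 lower), and what they measure was not examined.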

How the results depend on the processing

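The comparison with siNeg of the own run was the only alternative fit chosen after results had been seen. The planned slide term was not run, because slide numbers were not found in the files used. The cause of the moves below was not tested unless one is named.

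Counts moved by more than 1.5 times in few settings. With every kept probe tested on its own the unit changed, from 11437 genes to 19738 probes, so those counts do not compare directly. Of the probes, 10038 (siSUPT6H), 12871 (siSF3B1) and 9506 (siHNRNPH1) were called, where the genes called were 6551, 7950 and 6187. For all 3 siSF3B1 siRNAs 8317 probes were called (5414 genes), with 12920, 12558 and 14562 probes for the differences between targets, and 6840 between siNeg sets. With siRNA means as replicates 2450, 4924 and 1895 genes were left, and with the siRNA and siNeg set as a random block (correlation 0.511) 3293 with siSUPT6H and 2790 with siHNRNPH1. Asking for at least 1.5-fold left 2247, 4009 and 1982, and 1274, 3027 and 996 with each siRNA. Between siSUPT6H and siHNRNPH1 own-run values called 3462 of 7671. Between siNeg and Untreated 1134 were called in the authors' values, 849 with set 1 and 4456 with set 2, in place of 1745. Array weights gave 5060 genes among siSUPT6H siRNAs, 1488 among siSF3B1 siRNAs and 1746 between siNeg sets, and the authors' values 1882 among siSF3B1 siRNAs. Of the gene list tests, 23 called at first, 13 were called with an estimated correlation and 64 with fry, which tests against no change where camera tests against other genes.

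In the other settings the counts stayed within 1.5 times: 15 of 19 for siSUPT6H (5333 to 7023), 16 of 19 for siSF3B1 (5353 to 8095) and 15 of 19 for siHNRNPH1 (4623 to 6674). For all 9 siRNAs all 10 did (466 to 700). The targeted mRNAs were lower in 13 of 13 settings each, SUPT6H from -1.77 to -0.72 (the smallest without background correction), SF3B1 from -1.67 to -1.12 and HNRNPH1 from -1.35 to -1.06.

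Signs turned over for a few results. FLI1 with siSUPT6H was 0 in the authors' values, -0.01 against set 1 or in own-run values and -0.23 against Untreated, HNRNPF with siSUPT6H was -0.29 against Untreated, and PTMA between siNeg and Untreated was 0.09 in the authors' values and 0.10 with set 1 or in own-run values. For lists with siSF3B1 fry took the other sign for EWS-FLI1 activated targets (median 0.04), DNA replication and G1/S genes (-0.02), intronless genes (-0.07), neuronal differentiation genes (0.02) and extracellular matrix genes (-0.05), and DNA replication genes stood at -0.35 against Untreated. Of 9148 values for single gene results 9039 kept the call and sign, 91 lost the call, 10 gained it and 8 changed sign; of 792 list values these were 703, 20, 63 and 6.

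Leaving out 1 of 36 arrays at a time gave 6183 to 6674 genes for siSUPT6H, 7668 to 7959 for siSF3B1 and 5768 to 6290 for siHNRNPH1. Between siNeg and Untreated the range was 951 to 2469, with 1135, 951 and 967 without Untreated replicate 1, 2 and 3, and among siSF3B1 siRNAs 487 to 979, with 487, 512 and 534 without A3 replicate 1, 2 and 3. EWSR1 with siHNRNPH1 lost its call without any of 27 arrays (adjusted p up to 0.143, without siHNRNPH1_A3 replicate 1). HNRNPH1 with siSF3B1 lost it without siNeg replicate 3, 4, 5 or 6, A2 replicate 1 or 3, A3 replicate 2 or Q3 replicate 1 (adjusted p = 0.0689, 0.127, 0.0622, 0.095, 0.0521, 0.0599, 0.0664 and 0.0908). Between siNeg and Untreated PTMA lost it without Untreated replicate 1, 2 or 3 or siNeg replicate 4, 5 or 6 (adjusted p = 0.0762, 0.0821, 0.104, 0.084, 0.0861 and 0.0806), FLI1 without Untreated replicate 2 (-0.70, adjusted p = 0.0849) and DNAJB4 without Untreated replicate 1 (-0.56, adjusted p = 0.0564). Gene list tests were not repeated with arrays left out.

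Replicate numbers are shared between groups, and with the replicate number as a block 6540, 7929 and 6172 genes were called, 1716 between siNeg and Untreated and 4240 between siNeg sets. Residuals showed weak pairing: arrays of the same number in different groups correlated at 0.017 on average (others -0.008, one-sided permutation p = 0.0038, single pairs -0.13 to 0.27), and for 23 of 36 arrays the best match in another group had the same number (12 on average when permuted, p = 0.0035). The highest mean over a pair of groups was 0.208. This permutation was added after the results had been seen.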

Other observations

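The small RNA classes and the tests between targets for them were chosen only after the results had been seen; the tests of dim probes, of the normalization, of host transcripts and of unspliced host RNA were fixed before their values were computed, and the matched lists in the authors' values after.

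Classes of small non-coding RNA genes were counted and compared between targets. Against siNeg only the snoRNA class with siSF3B1 was tested, by the matched random lists given below. With siSF3B1 122 of 134 snoRNA genes rose and 0 fell (median 1.27, own-run 1.34), 113 of them with each of the 3 siRNAs. With siSUPT6H 46 rose and 11 fell (median 0.13), with siHNRNPH1 51 rose and 8 fell (0.16), and between siNeg and Untreated 1 rose and 9 fell. A dim probe could pass the detection filter through the siSF3B1 arrays alone, which favours rises there. The class was not counted without that filter, but the matched random lists were drawn from genes that passed it too. The class was higher with siSF3B1 than with siSUPT6H (median difference -1.18 for siSUPT6H minus siSF3B1, adjusted p = 1.94e-28) or siHNRNPH1 (1.01, adjusted p = 1.05e-27), both of which held with an estimated correlation (adjusted p = 1.64e-06). Of 16 scaRNA genes, which guide the modification of snRNAs in Cajal bodies, 12 rose and 1 fell with siSUPT6H (median 1.42), 13 with siSF3B1 (0.61) and 14 with siHNRNPH1 (1.91). They were lower with siSF3B1 than with siHNRNPH1 (-0.81, adjusted p = 0.00856), and with siSUPT6H than with siHNRNPH1 (-0.50, adjusted p = 0.00284), differences lost with an estimated correlation (adjusted p = 0.188 and 0.151). SCARNA11 stood at 1.69, 0.29 and 2.78 and SCARNA9 at 1.93, 0.05 and 0.98 in the order siSUPT6H, siSF3B1, siHNRNPH1. Of 13 snRNA genes 10, 12 and 10 rose (medians 0.85, 1.13 and 0.84; SNAR-A1 fell with siSF3B1, -0.47), among them RNU4ATAC (1.56, 1.91 and 1.22), RN7SK (0.92, 1.68 and 1.19), which holds the elongation factor P-TEFb inactive, and RNU6-1 (0.74, 1.18 and 0.54). In siNeg against Untreated 4 of the snRNA genes fell and 0 rose (median -0.26, RN7SK -0.35), while scaRNA genes stood at -0.03 (1 higher, 1 lower). The 13 snRNA genes include copies of 1 RNA and are not all separate. RNU1-1, RNU1-3, RNVU1-7 and RNVU1-18 are such copies, and stood at -0.47, -0.38, -0.42 and -0.36 in siNeg against Untreated. Small RNAs outside these classes varied. RMRP rose with each target (0.96, 0.90 and 0.89), as did RNY5 (0.62, 1.01 and 0.81). RNY4 fell with siSUPT6H (-0.61) and siHNRNPH1 (-0.93), and VTRNA1-1 was called with none. Of 237 lncRNA genes 67, 56 and 32 were higher and 39, 64 and 42 lower (medians 0.09, 0.00 and -0.04).

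Several sources of the snoRNA rise with siSF3B1 were tested. Dim probes are excluded, since the highest median of 10000 random lists of the same size and mean level was 0.08. The normalization used here bears on its size, since the class median in the authors' values was 0.61, against 1.34 here with the same control arrays, but not on its presence: 132 of 134 genes lay above 0 in the authors' values, where the highest matched list reached 0.05. More host transcript is excluded as the whole cause, as the 62 measured genes that contain a snoRNA gene had a median of -0.05 (95% interval -0.23 to 0.17; 19 higher, 25 lower), although the hosts SNHG17 (2.74) and SNHG1 (1.89) rose. Unspliced host RNA that carries the snoRNA sequence is argued against only for the 6 snoRNA genes inside no other gene. They had a median of 1.56 against 1.26 for the other 128. Of these 6, 3 are near-identical (SNORD3A 1.78, SNORD3C 1.68, SNORD3D 2.03), SNORA50C stood at 0.61 and RNU105C was not called (0.30, adjusted p = 0.0964). They are too few separate genes to speak for the other 128, for which unspliced host RNA could still be the cause or a part of it. Those 128 were placed inside a gene by position alone, without strand or introns.

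The fusion partners EWSR1 and FLI1 moved apart with siSF3B1, EWSR1 to -1.06 and FLI1 to 1.58 (own-run -1.04 and 0.98). With siHNRNPH1 the EWS-FLI1 repressed targets rose (median 1.43), a call that held with an estimated correlation, and the activated ones were lower (-0.26), a call lost with it (adjusted p = 0.11). EWSR1 stood there at -0.18 and FLI1 at -0.92 (adjusted p = 1.66e-05), -0.31 in own-run values (adjusted p = 0.0521) or -0.08 in the authors' values (adjusted p = 0.374). Whether the fusion protein fell was not measured here.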
